A study of Homo sapiens with 6 samples.

How the data were processed

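Human endometrial stromal cells isolated from menstrual fluid of 3 donors were cultured to passage 6 and transfected for 48 h with 100 nM of an siRNA pool, non-targeting (siNT) or against SRF (siSRF). They were collected after 3 more days in medium with 2% charcoal-stripped serum, per the labels. Each of the 6 libraries is 1 donor under 1 pool. Groups and replicate numbers come from the sample titles, where libraries with the same number share a cell preparation, and replicates are therefore 3 separate donors. The siRNA sequences are not given in the sources used here.

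Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.39 and aligned with HISAT2 2.2.1, alignments were sorted with SAMtools 1.16.1, and genes were counted with featureCounts 2.0.6 of the Subread package. DESeq2 1.38.2 in R 4.2.2 followed. The notes list both the hg38 human and the mm10 mouse builds, and coordinates printed here are those of the GRCh38 RefSeq annotation, matched by symbol. The settings for strand, for reads with several matches and for the DESeq2 design formula are not given in the sources used here, so values of genes with near-identical copies (actins, ribosomal proteins) carry that uncertainty. The deposited raw table holds the read count of each gene symbol in each library (unit count), with 59235 symbols, of which 57827 match a RefSeq name. The deposited normalized table holds a signal, and was checked to equal the raw counts divided by DESeq2 size factors (1.0014, 1.0457 and 1.3922 for siNT, 0.85029, 0.89031 and 0.93176 for siSRF). The largest relative difference was 4.9e-10 over its 28451 genes, those with at least 6 counts in all. The tests used the raw counts, since the normalized table adds no information to them.

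Total counts per library ranged from 64642476 to 103866408. XIST, TSIX, their neighbours JPX and FTX, and genes of the Y chromosome (590 symbols left out in all) stayed in the library sizes but were not tested. Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and in Python 3.11.15. The edgeR quasi-likelihood fit used TMM factors and filterByExpr (minimum count 10, minimum total 15), which kept 18971 genes. Adjusted p-values are Benjamini-Hochberg values from edgeR unless another tool is named, and the threshold was 0.05. CPM values use TMM library sizes. The planned fit compared the groups without a donor term, and the fit with the donor as a block was set beside it in advance. Pairing was checked on the data: after removal of group means, libraries of the same number correlated across genes at 0.762, 0.707 and 0.785, and those of different numbers between -0.483 and -0.259. Removal of means over 3 libraries pushes the latter below 0 once the former lie above it, so their negative sign is no separate evidence. Tested on simulated data with 18604 genes, the blocked fit recovered all of 100 genes changed by 1 on the log2 scale and 84 of 100 changed by 0.5, with 6.6% of its calls false, and the unpaired fit recovered 11 and 0. The simulated counts were drawn from the blocked fit itself, with the same change in every donor and changed genes of at least 5 CPM only. That layout favours the block in advance, and its rates need not hold for the real comparison. P-values rest on 3 donors, and an exact unpaired permutation test of 3 against 3 values cannot go below 0.1. For 3 pairs, the layout of the blocked fit, the limit of an exact test is higher still.

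There were 34 gene lists written from general knowledge of SRF and of endometrial stroma, none of them chosen on these samples. They cover targets of SRF and MRTF, immediate early genes, SRF cofactors, YAP targets, actin regulators, focal adhesion, smooth muscle and pericyte markers, matrix, basement membrane, proteases, TGF-beta and BMP response, growth factors, WNT pathway, decidual markers, and steroid receptors with HOX genes. The others cover DNA replication, mitosis, p53 targets, NF-kB, interferon, unfolded protein response, cholesterol, fatty acids, glycolysis, oxidative phosphorylation, lysosome, ribosome, mitochondrial transcripts, long noncoding RNAs, and markers of mesenchymal, epithelial, endothelial, immune and blood cells. Lists were tested with limma camera on log2 CPM (prior count 2) at a preset correlation of 0.01, beside camera with an estimated correlation and fry, each adjusted over the lists. With an estimated correlation, camera takes its p-values on the few residual degrees of freedom of 6 libraries. A call lost there can reflect low power as well as correlation between members. Counts of members are from edgeR, over all genes and adjusted over the list alone.

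The rule for named genes took SRF, the 12 highest and 12 lowest log2 fold changes among called genes with a mean of at least 5 CPM and the same direction in 3 donors, and up to 4 members of each list with the smallest adjusted p. It always took ACTA2, TAGLN, CNN1, PRL, IGFBP1, FOXO1, HAND2, PGR and ESR1. Symbols that are identifiers or start with LOC, LINC or MIR, or hold -AS, -DT or -IT, were skipped in the first part. XIST, TSIX, Y-linked, HLA and KIR genes and genes with common deletions or null alleles were never named. Since the unpaired fit called no gene, the first part was empty there, and the same rule was applied to the blocked fit after that was seen. FHL2, the genes of the ERK list and the mitochondrial ribosomal RNAs were named after their values were seen.

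Alternatives covered the donor block, size factors, library size alone, filters on low counts, each library and each donor left out, DESeq2, limma voom, thresholds, prior counts and the list correlation. Added after the data were seen were the same choices within the blocked fit, libraries thinned to 1 total (64642476 counts), offsets for GC content and transcript length on 13223 annotated genes, and the removal of genes with the 7-base sequence TGCTAGT in the 3′ untranslated region (UTR). To search for such sequences, the log2 fold changes of 11240 genes of at least 1 CPM were regressed on each of 15566 7-base sequences found in at least 100 annotated 3′ UTRs, with UTR length and GC content as covariates. Tested on simulated data, a planted effect of -0.1 was recovered as the most negative in 38 of 40 trials.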

Results

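Gene expression was measured by strand-specific mRNA sequencing in stromal cells of the human endometrium, the inner lining of the uterus, grown in culture from the menstrual fluid of 3 donors. Cells of each donor received either a non-targeting siRNA pool (siNT) or a pool against SRF (siSRF). SRF, serum response factor, is a transcription factor known to drive genes of the actin cytoskeleton. The 6 libraries form 2 groups of 3, and libraries with the same replicate number share a donor. Total counts in siNT replicates 1, 2 and 3 were 82265883, 79985528 and 103866408. Those of the siSRF replicates were 66844718, 64642476 and 68311515, lower in every donor.

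The comparison of siSRF with siNT asked what loss of SRF does to the transcriptome of these cells. SRF mRNA (chromosome 6, 43171269 to 43181506, GRCh38) fell to 30.3%, 37.6% and 42.7% of the siNT level in donors 1, 2 and 3. Its mean was 73.5 ± 13.0 CPM (counts scaled to a common library size; SD, n = 3) in siNT and 26.6 ± 1.75 CPM (SD, n = 3) in siSRF. With the donor as a block in edgeR, the log2 fold change was -1.45 ± 0.0992 (SE) with adjusted p = 4.41e-06. Without the block it was -1.46 with adjusted p = 0.197, and the alternatives gave adjusted p from 1.71e-34 to 1. The unpaired DESeq2 fit gave 1.6e-12. The transcription factors that bind with SRF, the 6 genes MRTFA, MRTFB, MYOCD, ELK1, ELK3 and ELK4, gave no call in either direction, also when adjusted over the list alone (camera adjusted p = 0.414 without and 0.371 with the block). That list passed as higher in the unpaired fit without siNT replicate 2 (0.0437) or donor 2 (0.0137). MRTFA, a cofactor released by actin polymerisation, stood at 0.10 and ELK3, a ternary complex factor, at 0.25 (adjusted p = 0.542 and 0.117).

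Genes of the contractile apparatus were among those that fell furthest in siSRF, within the rule for named genes (a mean of at least 5 CPM and the same direction in 3 donors). ACTG2, an actin of visceral smooth muscle, fell from 207 ± 109 to 24.6 ± 7.22 CPM, CNN1 (calponin) from 328 ± 204 to 51.3 ± 22.5, ACTA2 (smooth muscle alpha-actin) from 1011 ± 584 to 169 ± 30.8, and TAGLN (transgelin) from 1849 ± 989 to 372 ± 149 (SD, n = 3). Their log2 fold changes were -2.98 ± 0.116, -2.60 ± 0.111, -2.45 ± 0.190 and -2.27 ± 0.101 (SE), with adjusted p = 7.55e-08, 9.96e-08, 1.37e-05 and 9.96e-08. On GRCh38 ACTG2 lies on chromosome 2 (73893008 to 73919865), CNN1 on chromosome 19 (11538851 to 11550323), ACTA2 on chromosome 10 (88935074 to 88991337) and TAGLN on chromosome 11 (117199294 to 117207465). The other genes among the 12 that fell furthest under that rule were WFDC1, DES, RHOJ, NEFL, LMOD1, ACTC1, SPOCD1 and CHI3L1, between -2.75 and -1.99. Among them DES (desmin) is an intermediate filament of muscle, LMOD1 nucleates actin filaments and ACTC1 is the cardiac actin. RHOJ is a small GTPase of the Rho family, NEFL a neurofilament subunit and CHI3L1 a secreted glycoprotein. The NEFL call was lost without donor 1 (adjusted p = 0.0521). Reads shared between the near-identical actin genes are a limit on their separate values, since the handling of reads with several matches is not given in the sources used here.

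**Figure D1:**
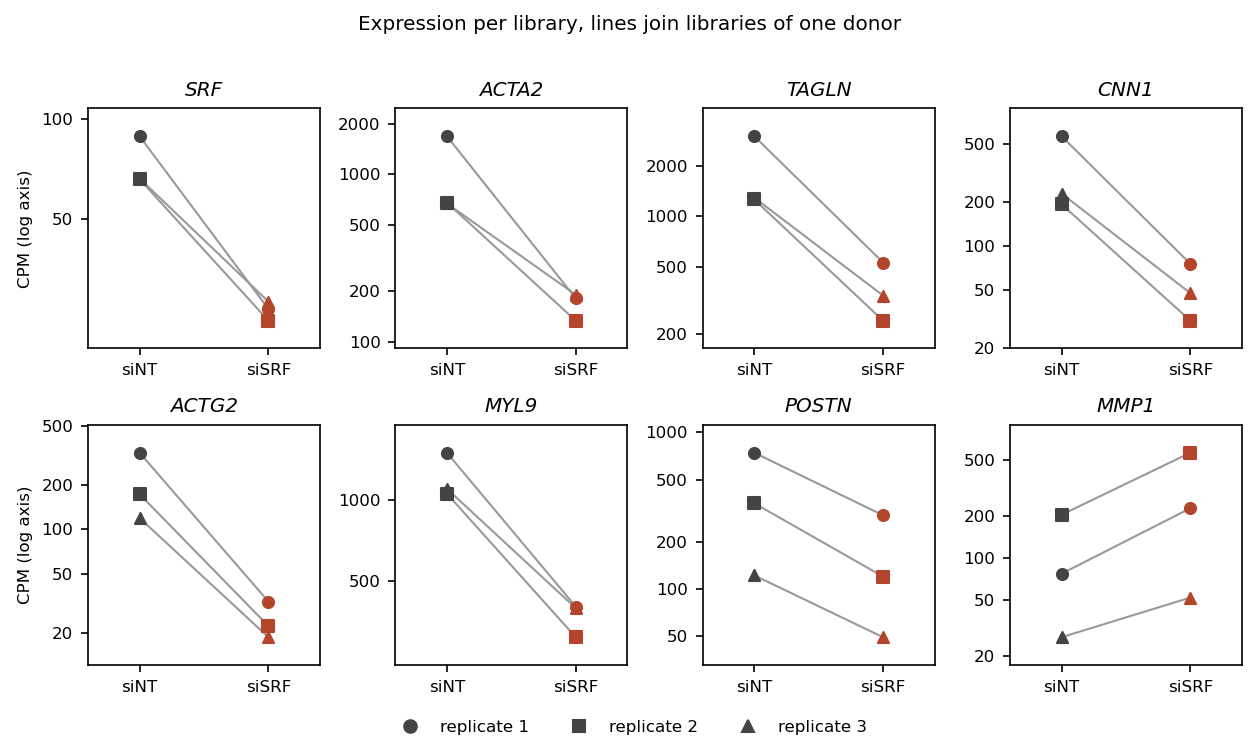
CPM (log axis) of SRF and 7 other genes in each of the 6 libraries, with lines that join the libraries of 1 donor. SRF lies between 65.8 and 88.5 CPM in siNT and between 24.8 and 28.3 CPM in siSRF, while MMP1 lies higher in siSRF in each donor.

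The genes that rose furthest under the same rule included a Notch ligand, a collagenase and secreted morphogens. DLL4, a ligand of Notch receptors, rose from 2.51 ± 1.49 to 10.1 ± 3.46 CPM (SD, n = 3; log2 fold change 2.07 ± 0.174, SE, adjusted p = 2.16e-05). NPTX1, a secreted pentraxin, rose from 32.3 ± 17.0 to 99.8 ± 41.0 CPM (1.65 ± 0.120, adjusted p = 7.81e-06). MMP1, the interstitial collagenase, rose from 102 ± 90.5 to 280 ± 259 CPM (1.32 ± 0.108, adjusted p = 1.82e-05), with log2 ratios of 1.55, 1.47 and 0.94 in donors 1, 2 and 3. HSD17B2, which inactivates estradiol, rose by 1.83 on the log2 scale. The other 8 of the 12 genes that rose furthest among those of at least 5 CPM were TENM4, PLCH1, KCNN2, WNT2B, CFH, BMP4, IQGAP2 and ABCA6, from 1.22 down to 1.01. WNT2B and BMP4 are secreted morphogens, CFH a regulator of complement and KCNN2 a calcium-activated potassium channel.

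With the donor as a block, edgeR called 1275 of 18971 tested genes, 404 higher and 871 lower in siSRF. Of these, 43 were higher and 175 lower by at least 1 on the log2 scale. Without the block, the fit planned before the data were examined, edgeR called 0 genes, with 391 higher and 691 lower at an unadjusted p below 0.05. Other tools without the block called 147 genes (DESeq2, 19 higher and 128 lower) and 0 genes (limma voom). With the block, DESeq2 called 1305 genes (448 higher, 857 lower) and limma voom 1305. The split between higher and lower genes depended on the scaling and on bias correction. Library size alone gave 665 higher and 691 lower. Offsets for GC content and length on annotated genes gave 604 higher and 868 lower, against 355 and 764 on the same genes without offsets. Leaving out donor 3 lowered the blocked count to 820 (224 higher, 596 lower), and leaving out donor 1 to 962 (260 higher, 702 lower). Unless the unpaired fit is named, each gene said to have risen or fallen passed edgeR with the donor block at an adjusted p below 0.05.

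**Figure D2:**
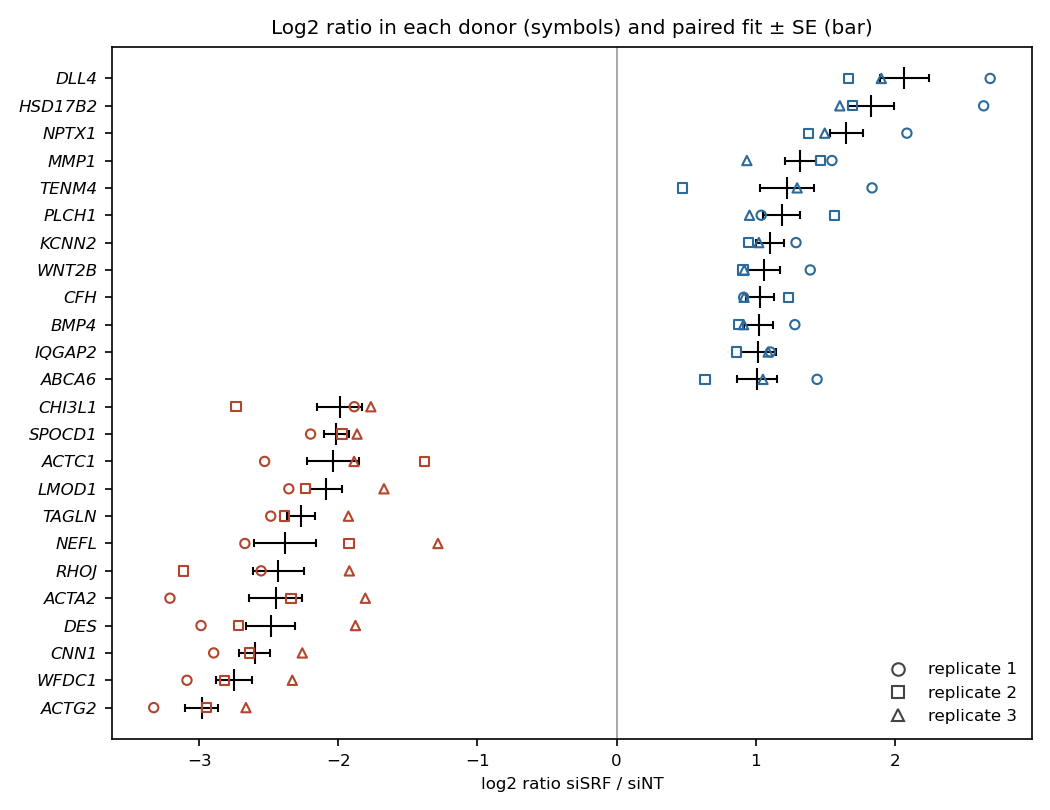
Log2 ratio of siSRF over siNT for 24 genes, the 12 that fell and the 12 that rose furthest among called genes of at least 5 CPM with the same direction in 3 donors, with a symbol for each donor and a bar for the edgeR estimate with the donor block ± SE. The estimates run from -2.98 for ACTG2 to 2.07 for DLL4.

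Most tested targets of SRF and its MRTF cofactors fell. Of 33 tested list members, 23 fell and 1 rose over all genes, and 29 fell and 1 rose when adjusted over the list alone. MYL9, the regulatory light chain of myosin, fell from 1225 ± 247 to 368 ± 52.2 CPM (SD, n = 3; log2 fold change -1.73). PDLIM7, an adaptor on actin stress fibres, fell by 1.25. FHL2, a LIM-domain protein, was the member that rose (0.32, adjusted p = 0.0242), and was picked out after its value was seen. The median log2 fold change was -0.69, and -0.90, -0.68 and -0.58 in donors 1, 2 and 3. The camera test placed the list below other genes with adjusted p = 4.11e-22 without the donor block and 2.62e-33 with it. Neither call held with an estimated correlation between members (adjusted p = 0.586 without the block and adjusted p = 0.604 with it, with an estimated correlation). That setting has little power with so few libraries. In the unpaired fit 1 member rose and 19 fell when adjusted over the list alone, and 0 passed over all genes.

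Some other actin regulators and adhesion genes also fell. Among 26 actin regulators 9 fell and 0 rose with the block, and 15 fell and 1 rose adjusted over the list alone. ARPC5 and ACTR3, subunits of the branching Arp2/3 complex, fell by 0.65 and 0.62, CFL2, a severing cofilin, by 0.59, and CAP1, which recycles actin monomers, by 0.48. ARPC5, ACTR3 and CFL2 carry the 7-base sequence TGCTAGT in the 3′ untranslated region, a class of transcripts that was lower in siSRF as a whole. The actin regulator list passed camera without the block (adjusted p = 2.50e-04) and with it (adjusted p = 1.07e-07), but not with an estimated correlation (adjusted p = 0.757 and adjusted p = 0.604), nor in the unpaired fit without siNT replicate 1 (0.203). Of 23 focal adhesion and integrin genes 6 fell and 1 rose, and 10 fell and 3 rose adjusted over the list alone. TNS1 (tensin) fell by 1.10, LIMS2, a partner of integrin-linked kinase, by 0.97, FERMT2 (kindlin-2), which also carries the 7-base site, by 0.79, and ITGAV, the integrin alpha-V chain, by 0.52. That list gave adjusted p = 0.0340 without the block and 0.00957 with it, against adjusted p = 0.757 and adjusted p = 0.604 with an estimated correlation. The unpaired call was lost without siNT replicate 1 (0.203), siNT replicate 2 (0.178), siSRF replicate 3 (0.154) or donor 2 (0.154).

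Of 12 markers of smooth muscle and pericytes outside the SRF list 3 fell and 0 rose, and 5 fell adjusted over the list alone, with a median of -0.21. MCAM, an adhesion molecule of pericytes, fell from 142 ± 104.2 to 39.4 ± 15.9 CPM (SD, n = 3; log2 fold change -1.69), SYNPO2, an actin-binding protein, by 1.32, and CSPG4 (NG2) by 1.01. Camera gave adjusted p = 0.00380 and 0.000160 without and with the block, and adjusted p = 0.586 and adjusted p = 0.604 with an estimated correlation.

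**Figure D3:**
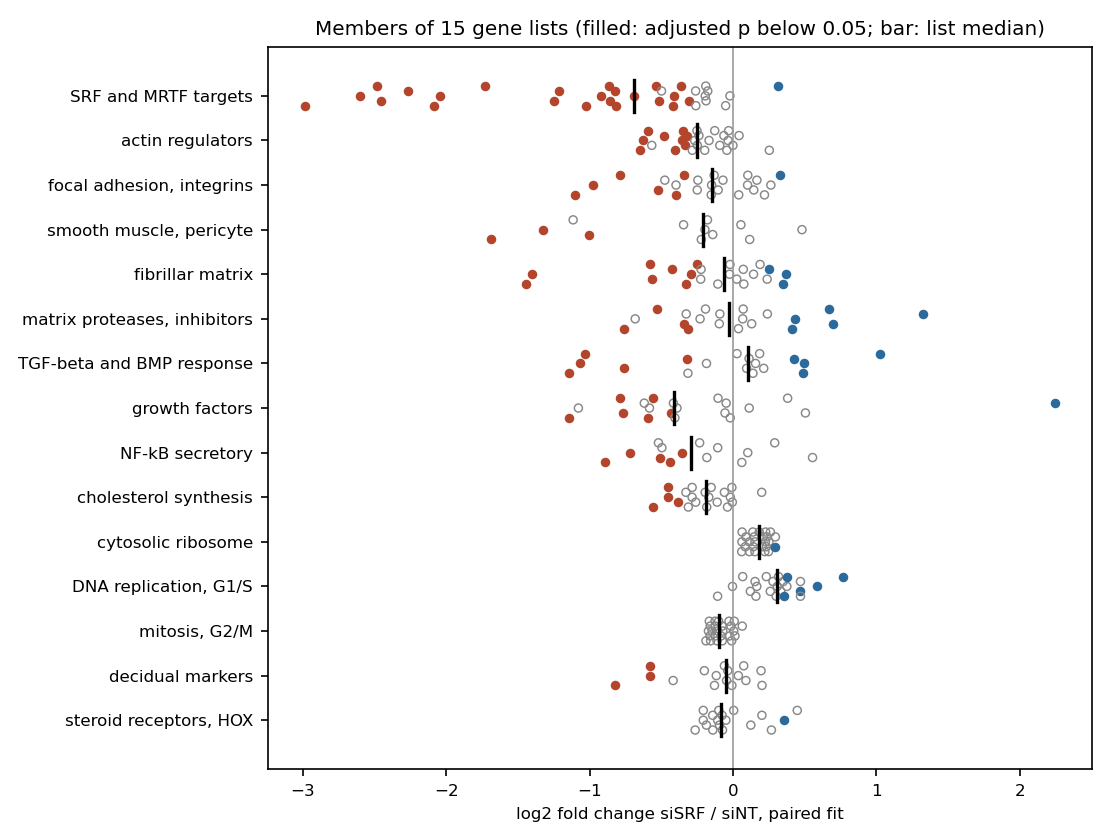
Log2 fold changes of siSRF over siNT (edgeR with the donor block) for the members of 15 gene lists, filled where the adjusted p is below 0.05, with a bar at each list median. SRF and MRTF targets have the lowest median (-0.69), and the medians of decidual markers and of matrix proteases (-0.05 and -0.03) lie above 0 when libraries are scaled by their size alone.

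Matrix genes moved in both directions. Of 22 fibrillar matrix genes 8 fell and 3 rose, and 10 fell and 5 rose adjusted over the list alone, but the list missed the camera threshold (adjusted p = 0.459 without and 0.0881 with the block). It passed as lower with the block when donor 2 (0.0147) or donor 3 (0.00760) was left out, or with no filter on low counts (1.09e-04). POSTN (periostin) fell from 406 ± 314 to 155 ± 127 CPM (SD, n = 3; log2 fold change -1.40) and TNC (tenascin-C) from 1107 ± 258 to 401 ± 37.5 CPM (-1.45). FN1 (fibronectin), a carrier of the 7-base site, fell by 0.56 and was not called by DESeq2 with the block (adjusted p = 0.202). COL6A2, a chain of collagen VI, rose by 0.37, a call lost with correction for GC content and length. Among 15 basement membrane genes 1 fell and 1 rose, and 4 fell and 5 rose adjusted over the list alone (camera adjusted p = 0.760 and 0.799). These were COL4A1, a collagen IV chain with the 7-base site (-0.53), and the linker protein NID2 (0.49).

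Proteases that remodel the matrix also moved both ways, MMP1 furthest. Of 20 proteases and inhibitors 5 rose and 4 fell, and 6 rose and 7 fell adjusted over the list alone (camera adjusted p = 0.760 and 0.854). Their median (-0.03) and mean (0.03) differed in sign, and the median turned to 0.03 with library size alone and 0.08 without donor 2, and was -0.12 without donor 1, -0.10 with no filter and -0.09 over genes without the 7-base site. MMP19 rose by 0.41 and PLAU (urokinase) by 0.67, whereas ADAMTS1, which cleaves versican, fell by 0.76 and ADAM12 by 0.53. Without donor 2 the list passed with the block as higher (adjusted p = 0.0385), and without donor 1 it passed in the unpaired fit as lower (0.0120). In the TGF-beta and BMP list 4 of 18 genes rose and 5 fell, and 4 rose and 6 fell adjusted over the list alone (camera adjusted p = 0.760 without and 0.927 with the block; median 0.10, mean -0.08). That median turned to -0.04 without donor 1 and was 0.06 without the block and 0.16 with library size alone. The receptor chain TGFBR1 fell by 1.14 and INHBA, the activin A subunit, by 1.03, while TGFBR2 rose by 0.50 and TGFBI by 0.49.

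Immediate early genes, another class of SRF targets, and targets of the coactivator YAP did not pass as lists in either fit with all libraries and the filter on low counts. Both passed as lower with the block and no filter (adjusted p = 0.0399 for each). Of 9 immediate early genes 2 fell, and 3 fell adjusted over the list alone (camera adjusted p = 0.340 and 0.304), and the list passed as lower in the unpaired fit without siNT replicate 1 (0.0157). EGR3, a zinc-finger transcription factor, fell by 1.32, and EGR1 by 0.40, a call lost without donor 1 (adjusted p = 0.144) or donor 2 (0.276), with GC and length offsets (0.0535) and with library size alone (0.0652). Of 22 YAP and TEAD targets 6 fell and 1 rose, and 6 fell and 2 rose adjusted over the list alone. CCN1, a matricellular protein, fell by 0.61, F3 (tissue factor), which carries the 7-base site, by 0.66, and IGFBP3, which binds insulin-like growth factors, by 0.62, while FJX1 rose by 0.53. The median of this list (0.07; 0.04 without donor 1 or 3, 0.13 with library size alone) and its mean (-0.16) differed in sign, and camera gave adjusted p = 0.760 and 0.562.

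Of 23 genes of DNA replication 5 rose and 0 fell, and 16 rose adjusted over the list alone, with a median of 0.31. E2F1, a transcription factor of S-phase entry, rose from 5.15 ± 2.00 to 7.78 ± 3.24 CPM (SD, n = 3; log2 fold change 0.58). MCM5, a helicase subunit, rose by 0.38, a call lost without any 1 donor (adjusted p from 0.0524 to 0.0695). Camera gave adjusted p = 0.000233 without and 1.09e-08 with the block for the replication list, against adjusted p = 0.757 and adjusted p = 0.604 with an estimated correlation. The unpaired call was lost without siNT replicate 3 (0.165) or siSRF replicate 2 (0.400). Of 25 mitotic genes 0 passed in edgeR with or without the block, also when adjusted over the list alone (camera adjusted p = 0.598 and 0.157). The mitotic list passed as lower with the block without donor 2 (0.0264), and in the unpaired fit without siNT replicate 3 (1.18e-05), siSRF replicate 2 (4.46e-04) or donor 3 (0.0321). It passed as higher without siSRF replicate 3 (0.0400).

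Of 25 cytosolic ribosomal protein genes 1 rose over all genes and 13 rose adjusted over the list alone, with a median of 0.18. RPLP0, a protein of the ribosomal stalk, rose by 0.29, a call lost without donor 2 (adjusted p = 0.0519) or donor 3 (0.128). Camera gave adjusted p = 2.34e-09 and 5.48e-08, and adjusted p = 0.586 and adjusted p = 0.604 with an estimated correlation. Among 20 p53 targets 3 rose and 1 fell, and 6 rose and 2 fell adjusted over the list alone. XPC, a DNA repair factor, rose by 0.36, a call lost without donor 3 (adjusted p = 0.0631), and TP53INP1 fell by 0.52. The p53 list passed camera without the block (adjusted p = 0.0340) but not with it (0.0671) nor with an estimated correlation (adjusted p = 0.586 without the block). Leaving out siNT replicate 1 or 2, siSRF replicate 1 or 3, or donor 1 or 3 ended the unpaired call (adjusted p = 0.0560, 0.104, 0.164, 0.170, 0.125 and 0.0544), as did a minimum of 1 CPM in 3 libraries (0.0643). With the block the list passed without donor 2 (0.0267), with library size alone (0.0319), with no filter (0.0248) and over genes without the 7-base site (0.0494).

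Of 20 genes of cholesterol synthesis 4 fell and 0 rose, and 8 fell adjusted over the list alone, with a median of -0.19 (-0.12 without donor 1 and -0.27 without donor 2). INSIG1, a sterol sensor, fell by 0.45, and STARD4, a sterol carrier, by 0.56, the latter lost without donor 1 (adjusted p = 0.0581). HMGCS1 (-0.45) and HMGCR (-0.38), enzymes of the mevalonate pathway, were lost without donor 1 (adjusted p = 0.0983 and 0.0982) and with library size alone (0.0619 and 0.0707). HMGCR carries the 7-base site and was also lost without donor 3 (0.0621). Camera gave adjusted p = 7.23e-05 without and 1.52e-04 with the block, and adjusted p = 0.586 and adjusted p = 0.604 with an estimated correlation. SCD, the stearoyl-CoA desaturase, also a carrier of the site, fell from 805 ± 118 to 395 ± 10.0 CPM (SD, n = 3; log2 fold change -1.02). The fatty acid and adipogenic list around SCD did not pass, with 3 of 20 genes lower and 1 higher, the same adjusted over the list alone (camera adjusted p = 0.459 and 0.312).

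Other metabolic and organelle lists missed the camera threshold in both fits. Of 22 glycolysis and hypoxia genes 2 fell, and 2 fell and 1 rose adjusted over the list alone (adjusted p = 0.289 and 0.160). PFKP, a phosphofructokinase, fell by 0.65. Of 20 nuclear genes of oxidative phosphorylation 1 fell, also when adjusted over the list alone (0.229 and 0.264; without siNT replicate 3, 0.0299 unpaired), namely CYCS (cytochrome c), by 0.51. The 13 transcripts encoded in mitochondrial DNA gave no call in edgeR over all genes or adjusted over the list alone (0.760 and 0.700; without siNT replicate 1, 0.00765 unpaired). Of 22 lysosome and autophagy genes 2 fell, also when adjusted over the list alone (0.760 and 0.799; without donor 1, 0.0400 unpaired), LAMP1, a lysosomal membrane protein, by 0.39 and MAP1LC3B, an autophagosome protein, by 0.50. The LAMP1 call was lost without donor 3 (adjusted p = 0.103). The unfolded protein list had 1 of 18 genes higher and 1 lower, also when adjusted over the list alone (0.760 and 0.799). Of 7 nuclear-retained long noncoding RNAs 1 fell, also adjusted over the list alone (0.459 and 0.638), namely MALAT1 (-0.61), which was lost without donor 1 (adjusted p = 0.126).

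Of 14 NF-kB targets 5 fell and 0 rose, and 8 fell adjusted over the list alone. IL33, an alarmin cytokine with the 7-base site, fell by 0.89, and ICAM1, a leukocyte adhesion molecule without it, by 0.44, the latter lost without donor 1 (adjusted p = 0.0683). Camera gave adjusted p = 0.0340 without and 9.98e-04 with the block, and adjusted p = 0.757 and adjusted p = 0.604 with an estimated correlation. The unpaired call was lost without siNT replicate 2 or 3, siSRF replicate 1 or 2, or donor 2 (0.202, 0.611, 0.458, 0.564 and 0.528), or with no filter (0.438). The blocked call was lost without donor 2 (adjusted p = 0.254) and over genes without the 7-base site (0.116), a site that 4 of the 14 carry. Of 20 angiogenic and other growth factors 6 fell and 1 rose, and 9 fell and 2 rose adjusted over the list alone, with a median of -0.41. FGF1 fell by 1.14, FGF7, a mitogen of epithelial cells, by 0.79, and VEGFC, a lymphangiogenic factor, by 0.44, whereas ANGPT2, a ligand of TIE2, rose from 0.475 ± 0.0984 to 2.48 ± 1.29 CPM (SD, n = 3; log2 fold change 2.24). This list gave adjusted p = 0.0340 and 0.00413, and adjusted p = 0.586 and adjusted p = 0.604 with an estimated correlation. Its unpaired call was lost without siNT replicate 2, siSRF replicate 1 or 3, or donor 2 (0.256, 0.0615, 0.138 and 0.122), or with a minimum of 1 CPM in 3 libraries (0.0643).

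Of 25 interferon response genes tested 2 fell, the guanylate-binding proteins GBP1 (-0.89) and GBP2 (-0.74), and 3 fell adjusted over the list alone. Camera gave adjusted p = 0.0569 without and 0.00413 with the block, and adjusted p = 0.757 and adjusted p = 0.604 with an estimated correlation. Without siNT replicate 1, siSRF replicate 3 or donor 2 the list also passed in the unpaired fit (0.00369, 0.00233 and 0.0293), as it did with library size alone (0.0215) or no filter (0.0356). In the WNT pathway 3 of 18 genes rose and 4 fell, and 3 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.947 and 0.638). FZD1, a Frizzled receptor, rose by 0.65, and WNT2, a secreted ligand, fell by 0.65.

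Decidual markers and steroid receptors, which mark the hormone response of these cells, did not pass as lists in either fit with all libraries and the filter on low counts. Of 16 decidual genes 3 fell, also when adjusted over the list alone (camera adjusted p = 0.306 and 0.157). These were CRYAB, a small heat shock protein (-0.82), TIMP3, a protease inhibitor (-0.58), and WNT5A (-0.58), which DESeq2 with the block did not call (adjusted p = 0.187). Without donor 1 the decidual list passed with the block as lower (0.0214), and without siNT replicate 1 in the unpaired fit (0.00805). With no filter it passed as lower with the block (0.00165) and without it (0.0356). FOXO1 and HAND2, transcription factors of decidualization, stood at 0.07 and -0.12 (adjusted p = 0.790 and 0.544). The secreted decidual markers PRL and IGFBP1 had between 0 and 21 counts per library, too few for a fold change, with fewer in siSRF in each donor for both. Of 18 steroid receptor, coregulator and uterine HOX genes 1 rose, also adjusted over the list alone (camera adjusted p = 0.549 and 0.409; without donor 1, 0.0433 and 0.0467, as lower). That was GATA2 (0.35), lost without donor 1 (adjusted p = 0.106) or donor 3 (0.0544). The progesterone receptor PGR, with the 7-base site, was at -0.07 and the estrogen receptor ESR1 at 0.12 (adjusted p = 0.785 and 0.782).

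Stromal identity genes did not pass as a list, and markers of other cell types were scarce or mixed. Of 19 mesenchymal and stromal genes 5 fell and 1 rose, and 6 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.935 and 0.562; median 0.05, mean -0.06). That median turned to -0.04 without donor 1, and was 0.11 without donor 2 or with library size alone and 0.09 with GC and length offsets. PDGFRA, a receptor of stromal fibroblasts, rose by 0.48, and the cadherin CDH11 fell by 0.47. Of 11 epithelial markers tested 1 rose and 1 fell, also adjusted over the list alone (0.760 and 0.972), with KRT19, a keratin, at 142 ± 98.4 CPM in siNT and 262 ± 239 in siSRF (SD, n = 3; log2 fold change 0.73). The other was MUC1, a mucin (-0.45), lost without donor 1 (adjusted p = 0.0739) or donor 3 (0.379), in DESeq2 with the block (0.0608) and with library size alone (0.0761). All 3 called endothelial genes of 8 rose, also adjusted over the list alone (0.462 and 0.239), namely EGFL7, FLT1 and TEK (0.59, 0.35 and 0.51). Their calls were lost without 1 donor or more (adjusted p up to 0.0571, 0.147 and 0.140). The 8 immune markers tested gave no call over all genes or adjusted over the list alone (0.947 and 0.825), and 1 of 11 blood cell markers passed the filter on low counts, too few for camera.

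Across the 33 lists tested, camera passed 10 without the block (3 higher, 7 lower) and 10 with it (2 higher, 8 lower), and 9 passed in both. With an estimated correlation 0 lists passed in camera in either fit. Over the 10 lists that passed without the block, the estimates of that fit ran from -0.04 (smooth muscle and pericyte markers) to 0.719 (DNA replication). The fry test of a common direction gave smallest adjusted p = 0.126 without and 0.236 with the block, while its test of change in either direction passed 15 lists with the block. With an unadjusted p below 0.05 were 1 list in each fit for the estimated correlation, and 4 lists in each fit for fry's common direction.

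Libraries differed more between donors than between siRNA pools. Principal components 1 and 2 (45.7% and 31.4% of variance) separated the donors, and component 3 (12.5%) separated siSRF from siNT in each donor. Across the 18971 tested genes, which are not independent replicates, the log2 ratios of donors correlated at 0.268 to 0.315 (mean 0.298), and at a mean of 0.637 over genes of at least 5 CPM.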

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

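The alternatives within the blocked fit, apart from removal of the block and DESeq2, were chosen after the data were seen, and so were the tests of them. The unpaired count of 0 genes (0 higher, 0 lower, 0 by at least 1 on the log2 scale) moved to 1275 (404, 871, 218) with the donor block, 27 (2, 25, 22) with no filter, 147 (19, 128, 72) with DESeq2 and 1305 (448, 857, 161) with DESeq2 and the block. SRF (-1.46, adjusted p = 0.197) passed in these settings, at -1.45 (4.41e-06), -1.47 (0.00505), -1.46 (1.6e-12) and -1.45 (1.71e-34). From the blocked count of 1275 (404 higher, 871 lower, 218 by at least 1), removal of the block gave 0 (0, 0, 0), no filter 1934 (636 higher), a test against a log2 change of 1 gave 40 (6, 34, 40), and a threshold of 0.01 gave 612 (140, 472). Library size alone gave 665 higher, GC and length offsets 604 (355 on those genes without them) and a minimum of 1 CPM in 3 libraries 140 by at least 1. Without 1 donor the blocked counts ranged from 820 to 1324, with 224 to 502 higher. Lists that passed (10, and 7 to 12 without a library or donor) fell to 0 with an estimated correlation and to 0 with an estimated correlation and the block, where the SRF and MRTF list stood at adjusted p = 0.586 and 0.604. The mean correlation of donor ratios (0.298) moved to 0.267 with a prior count of 0.5 and to 0.637 over genes of at least 5 CPM. Without siSRF replicate 3 the mitotic list passed as higher (adjusted p = 0.0400), and over the other libraries and donors left out its adjusted p ranged from 1.18e-05 to 0.776. The cause of these moves was not tested, except that fewer or more genes tested, fewer donors or a stricter threshold act by construction. So do the few degrees of freedom of camera with an estimated correlation, and that correlation itself where it lies above the preset 0.01. Of 3086 comparisons for 225 named genes in the blocked fit, 2799 kept their side of the threshold (40 of them uncalled with a turned sign), 226 lost the call (136 without the block, 67 without a donor), 61 gained it and 0 called genes reversed. Of 560 comparisons for lists against the unpaired fit, 494 kept their side of the threshold (48 of them uncalled with a turned direction), 46 lost and 19 gained the call, and 1 reversed. Thinned to 1 depth, the blocked fit called 1230 genes, 1201 of them among the 1275. Depth limits genes near 0 counts, such as PRL and IGFBP1.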

Other observations

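The tests of TGCTAGT as a seed match and against chance among 7-base sequences, of SRF targets without that site or other than actins, and of ERK output were chosen only after the result was seen. The same holds for the refits at equal depth, with GC and length offsets, and without genes that carry the site.

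Several feedback regulators and transcription factors downstream of the ERK kinase pathway rose in siSRF. SPRY1 and SPRY4, inhibitors of receptor tyrosine kinase signalling, rose by 0.95 and 0.70 on the log2 scale, DUSP6, an ERK phosphatase, by 0.81, and ETV1, an ETS transcription factor, by 0.90 (edgeR with the donor block, n = 3 donors, all 3 in that direction). SPRY4 carries the 7-base site TGCTAGT in its 3′ UTR. These 4 genes drew attention first, and a list of 17 ERK output genes was then written from general knowledge. Of the 13 others, 8 rose and 1 fell, with a median of 0.38. PHLDA1 rose by 0.63, SPRY2 by 0.55, FOSL1 by 0.52 and CCND1 (cyclin D1) by 0.50, while the phosphatase DUSP5 fell by 0.55. The calls of ETV4 (0.54), ETV5 (0.35) and SPRED2 (0.38) were lost without donor 3 (adjusted p = 0.118, 0.486 and 0.140), ETV4 also without donor 1 (0.0643), and ETV5 also with other size factors, at equal depth, over annotated genes, over genes without the 7-base site and with a minimum of 1 CPM in 3 libraries (0.0502 to 0.0519). Camera gave p = 4.86e-05 for the 13 genes as a list with the block and 0.00259 without it, but p = 0.0848 with an estimated correlation.

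A candidate explanation for this pattern is higher ERK pathway output in cells with less SRF, a hypothesis found and tested on the same data. The count of 8 of 13 other members called higher met what higher output of the ERK pathway would need. Correction for GC content and transcript length left their median at 0.3788, which argues against such bias as the whole cause. Thinning to equal depth left that median at 0.3825, but thinning with rescaling hardly moves such medians, so depth was not tested by it. ERK activity itself was not measured, and a change in cell density or state under either pool stays open and untested.

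The fall of SRF and MRTF targets was set against depth, sequence bias and off-target sites. The median of the list was -0.6878 with libraries thinned to equal depth, close to -0.69 before. Thinning with rescaling hardly moves the fold changes of well-counted genes, so this value could not test depth. With GC and length offsets the median was -0.6976, which argues against sequence bias as the whole cause. The sequence TGCTAGT lies in the 3′ UTR of 2 of 33 members, and 21 of the 31 without it were called lower (67.7%, against 5.04% of other genes without it), so such sites are not the whole cause either. Of the 28 members other than actin genes 18 were called lower (64.3%, against 4.48% of genes outside the list), which argues against reads shared between actin genes as the whole cause. Loss of SRF, the factor known to bind these genes, may therefore lie behind the fall, as a hypothesis. Other effects of the pool, sites of its other siRNAs included, stay open and untested, as does the share of such reads in the values of the 5 actin members.

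Transcripts with the sequence TGCTAGT in the 3′ UTR were lower in siSRF. Over 827 such genes the adjusted slope was -0.09477 on the log2 scale per gene with a site (SE 0.0102). It was the most negative of 15566 sequences (z = -9.26) and first in each donor (-0.12, -0.09 and -0.07). Those that followed, TTGCTAG (z = -6.09) and GCTAGTA (-5.91), overlap it by a shift of 1 base. The first without such an overlap was TGTCTCT (-4.60). Chance among many sequences gave 0 of 1000 permutations as large (largest absolute z 5.83). Genes with the site differed by -0.09454 from genes without it that were matched on 3′ UTR length and GC content. The SD of that difference, over random draws of the matched partners only, was 0.00873. Neither chance among sequences nor UTR length and GC content therefore accounts for the whole effect. The slope of the same sequence in coding regions was -0.02 ± 0.0118 (SE), 4.64 times smaller, so microRNA-like seed matching by an siRNA of the SRF pool is a candidate explanation, and 1 copy lies in the SRF coding sequence (position 921 of 1524, exon 3). That copy alone tells little, since 18.8% of the sequences occur in the SRF transcript, and the siRNA sequences are not given in the sources used here.

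Of the genes with the site 16.2% were called lower in the blocked fit, against 5.67% of searched genes without it, and 1.81% against 3.21% were called higher. Without these genes the blocked fit called 1081 genes, 362 higher and 719 lower, and 10 lists passed camera, 9 of them among those that passed with all genes.

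The 6 libraries can be parted into 3 and 3 in 10 ways, too few for a share under 0.05. In the unpaired fit the real split called 0 genes and the highest other split 0, so that all 10 gave as many. In the blocked fit the real split called 1275 and the highest other 0, so that 1 of 10 gave as many. Only 4 of the 10 part all 3 pairs of libraries and are comparable with the block, and 1 of these 4 gave as many. In every other split the siRNA difference also adds to the residual spread, which lowers the calls. Of the lists, 10 passed without the block against a highest of 13 in another split (3 of 10 splits gave as many), and 10 with it against a highest of 10 (2 of 10). The real split is 1 of the 4 that part all 3 pairs, and the 3 others passed 5 to 10 lists with the block. Each of those 3 reverses 1 pair, so part of the siRNA difference stays in its contrast. The remaining 6 part 1 pair, and with the block they compare the pools in that donor alone. For SRF and MRTF targets the blocked camera test gave adjusted p = 2.62e-33 in the real split. It gave 1.81e-07, 0.000375 and 0.473 in the 3 others that part all pairs. In the 6 that rest on 1 donor it ranged from 7.5e-09 to 3.22e-06, with the real siRNA difference kept. Every other split thus keeps some of the siRNA difference, and none shows what the list tests give without it. These splits therefore cannot decide how far the real split stands apart for this list or for the count of lists.

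The 2 mitochondrial ribosomal RNAs, which carry no long poly(A) tail, were lower in siSRF, at -0.36 for RNR1 (adjusted p = 0.00918) and -0.25 for RNR2 (0.0317) on the log2 scale. The RNR1 call was lost without donor 2 (0.0536) or donor 3 (0.0996), and that of RNR2 without donor 3 (0.222) and with library size alone (0.0875).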
